A study of Mus musculus with 6 samples.

How the data were processed

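Total RNA of mouse hippocampus was extracted with Trizol, and biotin-labelled sense cDNA was made with a GeneChip WT terminal labelling kit, per the labels' protocols. The 6 samples were grouped by the genotype in their labels, 3 wild type and 3 Trpc4 knockout. The labels name replicates but do not state that each is a separate animal, so p-values measure the spread between these samples, which may be technical in part. The authors deposited 1 table of log2 expression values for all arrays, made with RMA and Affymetrix Power Tools per the submitters' processing notes. RMA in general corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set on the log2 scale. Versions, the array annotation and the genome build are not given in the sources used here. Because the arrays were normalized together, a change shared by most genes would not be visible. No raw scans were used, so signal could not be set against a measured background. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.0997.

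Probe sets were named from a platform annotation table, which can be old. Of 41345 probe sets, 23521 named 1 gene, 1814 named several and 16010 had no name in it. The first kind was tested, with the probe set of the highest mean signal standing for its gene, which gave 22180 genes. Of these, 21994 were found by gene number in a RefSeq table of assembly GRCm38.p6, and 0 symbols differed there. That table served only for names and for the order of genes along chromosomes, and no coordinates are printed.

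Knockout was compared with wild type by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. A count at an unadjusted p under 0.05 and at least 1.5-fold is given beside it and does not control false discoveries. Gene lists, written from general knowledge, were tested with camera at a preset correlation of 0.01 and adjusted over all 44 lists, each with at least 5 measured members. Fry was run as an alternative, and its mixed form tests change in either direction without comparing a list with other genes. They held 882 symbols, older synonyms included, of which 765 genes were measured. Camera sets the moderated statistics of a list against those of all other genes, so its direction need not be that of the mean log2 difference. It was down with a positive mean for CA2, CA3, striatum, microglia and blood cell markers, monoamine and acetylcholine receptors and glucocorticoid response genes. Median and mean differed in sign for the TRPC, CA2, striatum, thalamus and habenula, blood cell, oligodendrocyte precursor, neuropeptide and antigen presentation lists. A list score is the mean over members of each sample's deviation from the gene mean. Exact two-sided permutation tests over 3 against 3 samples cannot give a p under 0.1. The standard errors and 95% intervals come from the limma fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

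The design, the lists and the alternatives were fixed before the data were examined, and so was the rule for named genes. It names every measured TRPC gene, then the 10 largest rises and 10 largest falls among genes past the adjusted threshold whose groups do not overlap, leaving out predicted, clone, small RNA and receptor-cluster names. Where fewer than 10 qualify, it fills with the smallest unadjusted p among genes whose mean lies above the median of all probe sets (4.72) in at least 1 group. It adds up to 4 members per list with the smallest unadjusted p, and neighbours of Trpc4 past the threshold over their list. Since 0 genes passed, all rises and falls came from the fill. Cryab, Sox10, Myrf and Rps13, and in the closing section Zic1 and ND6, were chosen after their values were seen.

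The alternatives were quantile normalization, median centring, a replicate block, array weights, trend and robust variance, a filter on dim probe sets, all probe sets or their mean, other thresholds, leaving out each sample, an estimated correlation in camera, and fry. The fits were tested on simulated data with the 22180 genes. Of 50 genes changed by 0.5 on the log2 scale 18 were called, and of 50 changed by 1, 47 were called. The same simulated data also held 50 genes changed by 2 and 50 by 3, of which 48 and 50 were called. Many true changes make the adjusted threshold easier to reach. These shares therefore overstate what could be called in data with few changes, and a lack of calls does not exclude changes of that size. Of 21980 unchanged genes 6 were called. An unchanged list whose 20 genes shared a sample factor was called in 43 of 50 runs with the preset correlation and in 1 of 50 with the estimated one. In these runs a call was an unadjusted camera p under 0.05, not a p adjusted over lists. No correlated list with a true shift was simulated, so a call lost with an estimated correlation does not exclude a shift. Probe sets naming several genes or none, 17824 in all, were left out of the main comparison, and 0 of them passed the adjusted threshold, with 857 at an unadjusted p under 0.05 by limma.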

Results

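Gene expression was measured in the hippocampus of male mice on a C57BL/6J background at postnatal day 56. RNA from 3 wild-type samples and 3 samples carrying a deletion of Trpc4 was hybridised to Affymetrix expression arrays, 1 array per sample. Trpc4 encodes a receptor-operated cation channel of the TRPC family. Each array gave log2 signals for 41345 probe sets, and the array medians lay between 4.73 and 4.75. Pearson's r across probe sets was 0.985 to 0.988 for every pair of arrays, within and between genotypes, with probe sets not being independent replicates. No pair of arrays held identical columns. The comparison asked which transcripts differ in the hippocampus when Trpc4 is deleted, and all differences are given as knockout minus wild type.

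The Trpc4 signal was lower in all 3 knockout samples than in any wild-type sample. It was 8.12 ± 0.10 in wild type and 7.42 ± 0.12 in knockout on the log2 scale (SD, n = 3 each), measured by probe set 17397557. The difference was -0.70 with a standard error of 0.09, so that the knockout signal was 61.5% of the wild-type signal, and its 95% confidence interval ran from -0.92 to -0.48. As the gene fixed in advance as the target, Trpc4 fell with an unadjusted limma p of 8.87e-05 and an adjusted p of 0.000532 over the TRPC list alone. Over all genes tested its adjusted p was 0.738. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples can give. The knockout signal stayed above the array medians. The labels do not say which part of the gene was deleted, and probe positions were not used here, so a probe set partly or wholly outside the deletion would not check the genotype.

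None of the other 5 measured TRPC genes passed the threshold in knockout hippocampus, over all genes or adjusted over the list alone. Trpc5, a close relative of Trpc4, had a signal of 8.75 ± 0.04 in wild type and 8.82 ± 0.09 in knockout (SD, n = 3 each), a difference of 0.07 with a 95% interval of -0.12 to 0.25. Trpc1, which can join TRPC4 and TRPC5 in one channel, differed by 0.08 with an interval of -0.15 to 0.31. Trpc6 differed by 0.15 (interval -0.15 to 0.45), and Trpc7 by 0.07 (interval -0.25 to 0.40). Trpc2 differed by -0.02, with an interval of -0.29 to 0.24. Leaving out single samples moved Trpc5 between 0.03 (without knockout replicate 2) and 0.12 (without knockout replicate 1). Trpc1 lay between 0.0045 (without knockout replicate 2) and 0.14 (without knockout replicate 1), and Trpc6 between 0.07 (without knockout replicate 1) and 0.26 (without knockout replicate 2). The sign for Trpc7 turned without knockout replicate 1 (-0.05) or wild-type replicate 3 (-0.02). That for Trpc2 turned without wild-type replicate 1 (0.05), knockout replicate 1 (0.02) or knockout replicate 3 (0.04). Of the 20 other TRP channel genes measured, 0 passed adjusted over the list alone and 0 over all genes.

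**Figure D1:**
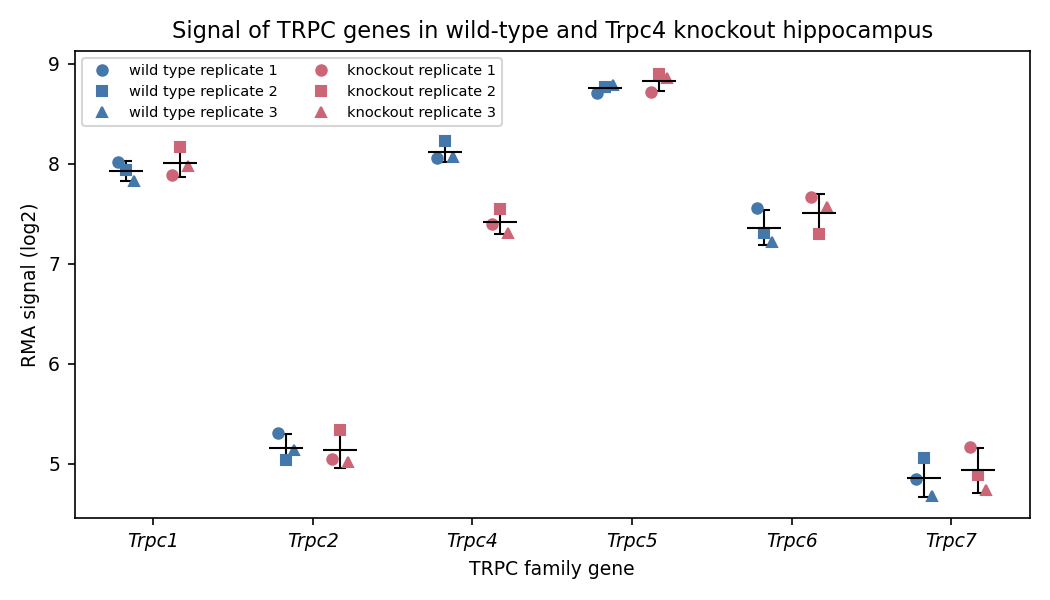
Log2 signal of each measured TRPC gene in the 3 wild-type and 3 knockout hippocampus samples, 1 point per array; horizontal lines are group means and bars 1 SD (n = 3). The Trpc4 points of the knockout lie near 7.42, below all wild-type points near 8.12, while the groups overlap for the other 5 genes.

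Across the 22180 genes tested, limma called 0 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.738. At an unadjusted p under 0.05 there were 1276 genes, 701 higher and 575 lower in knockout, where 5% of the genes tested is 1109. With quantile normalization the balance turned, to 646 higher and 656 lower, while with median centring it did not (658 higher and 618 lower). With a 1.5-fold limit added, 44 genes remained, 14 higher and 30 lower. All 3 knockout values lay on one side of all 3 wild-type values for 10.9% of genes, where chance gives 10%. The 44 became 78 without wild-type replicate 1, 71 without knockout replicate 1 and 78 without knockout replicate 3. Without knockout replicate 1 the adjusted count was 1, the dim ribosomal protein gene Rps13, at -2.24. This call hung on the sample left out. Rps13 differed by -0.72 without knockout replicate 3, and its highest unadjusted limma p with a sample left out was 0.352.

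Genes of small unadjusted p are given as values, since none of them passed the adjusted threshold (adjusted p 0.738 to 0.849). They are those with a signal above the median of all probe sets in at least 1 group, groups that do not overlap and no predicted or clone name. The lowest p of all genes was that of a dimmer one, Rps15, at -1.20 ± 0.15. Of those higher in all 3 knockout samples, the zinc finger gene Zfp180 differed by 0.70 ± 0.11 (log2 difference ± standard error), from 6.06 to 6.76. Tdrd5, a tudor domain gene known from the germline, differed by 0.56 ± 0.09 and the hair keratin gene Krt35 by 0.48 ± 0.10. The folate enzyme relative Mthfsl differed by 0.49 ± 0.10 and Borcs7, of a complex that positions lysosomes, by 0.45 ± 0.09. Tubd1, Loxl1, B9d1, Mrpl4 and Pcdhb2 differed by 0.34 to 0.38. Of those lower in all 3 knockout samples, Trpc4 had the lowest p and was followed by Mpeg1, a macrophage and microglia gene, at -0.58 ± 0.10. The iodotyrosine deiodinase gene Iyd differed by -0.36 ± 0.07, from 5.61 to 5.25, and Banf2 by -0.41 ± 0.09. The EF-hand protein gene Chp1 differed by -0.42 ± 0.10, Rpp25l by -0.43 ± 0.10, the ubiquitin ligase gene Trim59 by -0.45 ± 0.11, and the glycogen branching enzyme gene Gbe1 by -0.31 ± 0.07. Ranbp3l differed by -0.34 and Nipal4 by -0.33.

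Genes of myelinating oligodendrocytes had lower signals in the knockout samples as a group. All 19 measured genes of the oligodendrocyte and myelin list were lower, with a mean difference of -0.41 and a range of -0.82 to -0.12. Tspan2, a tetraspanin of oligodendrocytes, went from 9.47 ± 0.17 to 8.85 ± 0.28 (SD, n = 3 each). Aspa, the enzyme that cleaves N-acetylaspartate, differed by -0.68 ± 0.18 (standard error), the myelin enzyme gene Cnp by -0.44 ± 0.14 and the myelin membrane gene Opalin by -0.48 ± 0.15. The largest difference was that of the small heat shock protein gene Cryab, at -0.82, while the transcription factor genes Sox10 (-0.16) and Myrf (-0.12) differed least. Of the 19 genes, 9 passed adjusted over the list alone and 0 over all genes, and 15 had groups that did not overlap. The lowest adjusted p over the list alone was 0.0485 (limma), so all 9 lay just under the threshold of 0.05. The genes of this list varied together, with an estimated correlation of 0.807. The 9 are therefore not separate findings. Nor are the 15 independent, and they cannot be set against the 10% that chance gives for a single gene. The list was called by camera with the preset correlation at an adjusted p of 5.94e-16. Its call was lost with an estimated correlation (adjusted p = 0.811 with an estimated correlation). The list score was 0.20 ± 0.03 in wild type and -0.20 ± 0.29 in knockout (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest possible. The knockout samples differed among themselves, at -0.20, -0.49 and 0.08 for replicates 1 to 3, and without knockout replicate 2 the mean difference was -0.26 and that of Cryab -0.48. Sox10 lay between -0.33 (without knockout replicate 3) and -0.06 (without knockout replicate 1), and Myrf between -0.19 (without knockout replicate 3) and -0.07 (without knockout replicate 2).

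**Figure D2:**
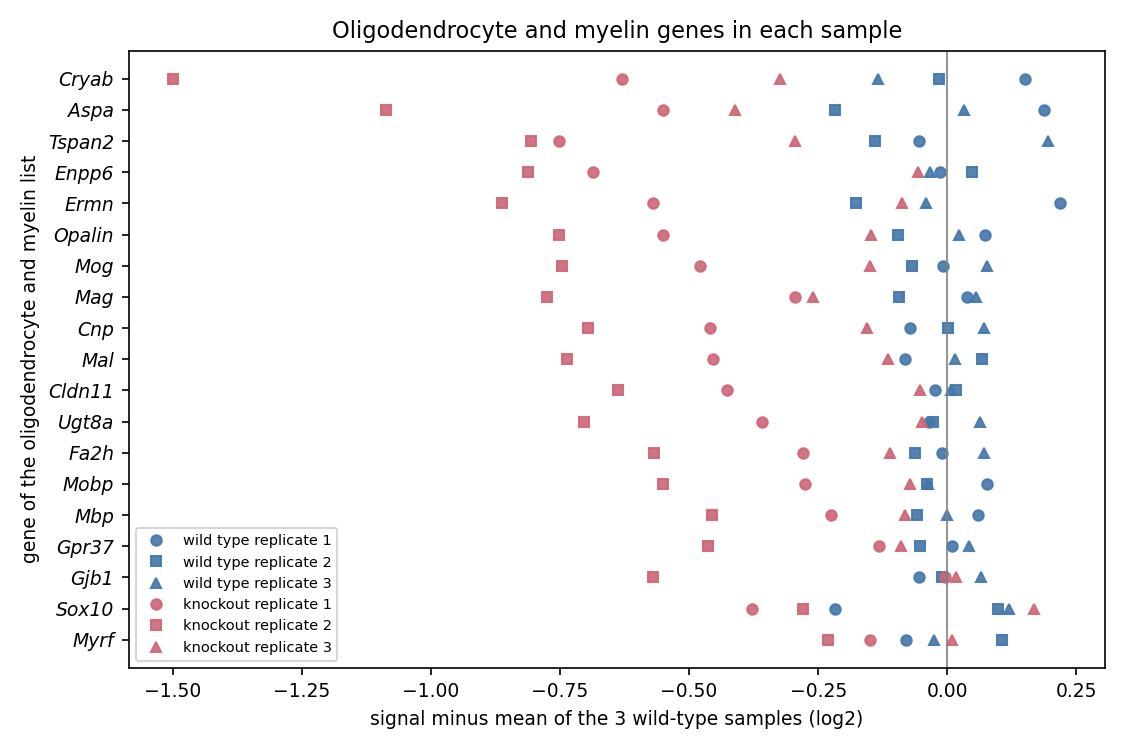
Signal of each of the 19 measured oligodendrocyte and myelin genes in each sample, as the log2 difference from the mean of the 3 wild-type samples, with colour for genotype and marker shape for replicate. Knockout replicate 2 lies lowest for most genes and knockout replicate 3 lies nearest to wild type, with list scores of -0.49 and 0.08.

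Dentate gyrus markers were higher in knockout for 14 of the 16 measured genes, with a mean difference of 0.12. Plk5 differed by 0.30 ± 0.09, the synaptic C1q-like gene C1ql2 by 0.28 ± 0.11, Maml2 by 0.20 ± 0.11 and Marcksl1 by 0.16 ± 0.09. Of the 16 genes, 0 passed adjusted over the list alone and 0 over all genes. Camera with the preset correlation called the list at an adjusted p of 0.0363, and the call was lost with an estimated correlation (adjusted p = 0.925 with an estimated correlation). It was also lost without wild-type replicate 2 (mean 0.08, adjusted p 0.507), wild-type replicate 3 (0.10, 0.217), knockout replicate 1 (0.13, 0.0563) or knockout replicate 2 (0.08, 0.285), and the mean was 0.19 without wild-type replicate 1. Maml2 differed by 0.13 without knockout replicate 2. The exact two-sided permutation p of the list score was 0.3. By sample, the dentate score was 0.05, 0.14 and -0.01 in knockout replicates 1 to 3, whose myelin scores were -0.20, -0.49 and 0.08. In wild-type replicates 1 to 3 it was 0.08, -0.15 and -0.11, with myelin scores of 0.21, 0.17 and 0.23.

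No other list of cell types or hippocampal fields was called by camera in the main comparison. Those called under another setting had adjusted p values of 0.620 to 0.962 there with an estimated correlation. Interneuron markers came closest, with 13 of 18 genes lower, a mean difference of -0.07 and an adjusted p of 0.0590, which became 0.0409 without wild-type replicate 3, 0.0417 with array weights, 0.0113 with trend and robust variance and 0.00975 with only probe sets above the median. Among them the homeobox genes Dlx2 and Dlx5 differed by -0.21 ± 0.09 and -0.29 ± 0.13, and the somatostatin gene Sst by -0.19 ± 0.12. Endothelial markers were lower for 13 of 17 genes (adjusted p 0.0802, and 0.0210 without wild-type replicate 2, 0.0229 without knockout replicate 3 or 0.0279 with only probe sets above the median), with the efflux transporter gene Abcb1a at -0.26 ± 0.09. Choroid plexus and ependyma markers were lower for 12 of 18 genes (adjusted p 0.0927, and 0.0357 without knockout replicate 3), with the transthyretin gene Ttr at -0.43 ± 0.18. Mural cell and fibroblast markers were lower for 11 of 18 genes (adjusted p 0.261, and 0.0472 without knockout replicate 3), with the smooth muscle actin gene Acta2 at -0.24 ± 0.09. CA1 markers were higher for 9 of 11 genes (adjusted p 0.487), although Wfs1 differed by -0.25 ± 0.08 and Mpped1 by 0.26 ± 0.09. CA2 markers went both ways, 4 of 8 higher (adjusted p 0.973), with Map3k15 at 0.30 ± 0.12 and Rgs14 at 0.23 ± 0.10. Of 13 CA3 markers, 8 were higher (adjusted p 0.976), with Cpne4 at 0.19 ± 0.08, and 1 passed adjusted over the list alone, Iyd, which was lower. This list passed the mixed fry test of change in either direction (adjusted p 0.0146). Oligodendrocyte precursor markers were lower for 5 of 12 genes (adjusted p 0.778), with Gpr17 at -0.26 ± 0.11 and Lhfpl3 at 0.18 ± 0.08. Astrocyte markers were lower for 12 of 19 genes (adjusted p 0.381), and microglia markers for 8 of 18 (adjusted p 0.973), among which the cathepsin gene Ctss differed by -0.29 ± 0.09 and Aif1 by 0.24 ± 0.10. The mean signals of Map3k15 and Aif1 lay below the median of all probe sets. Single samples carried part of several of these values. Without wild-type replicate 2, Dlx5 differed by -0.14 and Sst by -0.12. Without wild-type replicate 3, Sst differed by -0.30, Ttr by -0.27 and Aif1 by 0.15, and without knockout replicate 2, Gpr17 differed by -0.16.

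Lists of channels, calcium signalling and synaptic genes were not called by camera, and 0 of their genes passed over all genes or, outside the TRPC list, adjusted over the list alone. In the list of Gq, phospholipase C and store-operated calcium signalling, which acts upstream of TRPC channels, 18 of 26 genes were higher (adjusted p 0.612). Its member Plcb3 differed by -0.19 ± 0.08 and Gna11 by 0.16 ± 0.08. Calcium handling genes were higher for 16 of 27 (adjusted p 0.801), with the plasma membrane calcium pump gene Atp2b3 at 0.24 ± 0.10 and the kinase gene Camk2d at -0.28 ± 0.12. Voltage-gated calcium channel genes were higher for 13 of 17 (adjusted p 0.325), and Cacna1b differed by 0.14 ± 0.07. Potassium channel genes were higher for 16 of 26 (adjusted p 0.778). Ionotropic glutamate receptor genes were higher for 12 of 15 (adjusted p 0.309), with the NMDA receptor genes Grin2a and Grin2d both at 0.15 ± 0.09. GABA receptor genes were higher for 8 of 11 (adjusted p 0.778). Postsynaptic scaffold genes were higher for 17 of 24 (adjusted p 0.308), led by Nlgn2 at 0.19 ± 0.07, a neuroligin of inhibitory synapses. Synaptic vesicle genes were higher for 18 of 27 (adjusted p 0.343), with the vesicular glutamate transporter gene Slc17a7 at 0.15 ± 0.07. The TRPC list was not called by camera (adjusted p 0.778) and passed the mixed fry test (adjusted p 0.0143), with Trpc4 its only member past the list-alone threshold. As the list holds the deleted gene, this pass says nothing about its other members. Among monoamine and acetylcholine receptor genes (adjusted p 0.903), Chrna7 differed by 0.21 ± 0.07 and Drd4, whose mean signal lay below the median of all probe sets, by -0.24 ± 0.08. Without wild-type replicate 3, Atp2b3 differed by 0.15, Camk2d by -0.18 and Gna11 by 0.09. Grin2a differed by 0.24 without wild-type replicate 1, and Grin2d by 0.10 without knockout replicate 2.

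Immediate early genes, which neurons induce on activity, were lower for 19 of 33 genes, with a mean of -0.04 and an adjusted p of 0.308. Arc differed by -0.26 ± 0.12, Ier2, with a mean signal below the median of all probe sets, by -0.29 ± 0.13 and Ier5 by 0.16 ± 0.07. Without knockout replicate 2, Arc differed by -0.15 and Ier2 by -0.17. Without knockout replicate 1 the list was called, at a mean of -0.12 and an adjusted p of 0.000755 (adjusted p = 0.962 with an estimated correlation). Glucocorticoid response genes were higher for 12 of 21 (adjusted p 0.973), with the receptor gene Nr3c1 at -0.18 ± 0.08. Circadian clock genes were lower for 11 of 18 (adjusted p 0.334), with Arntl at 0.25 ± 0.08.

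**Figure D3:**
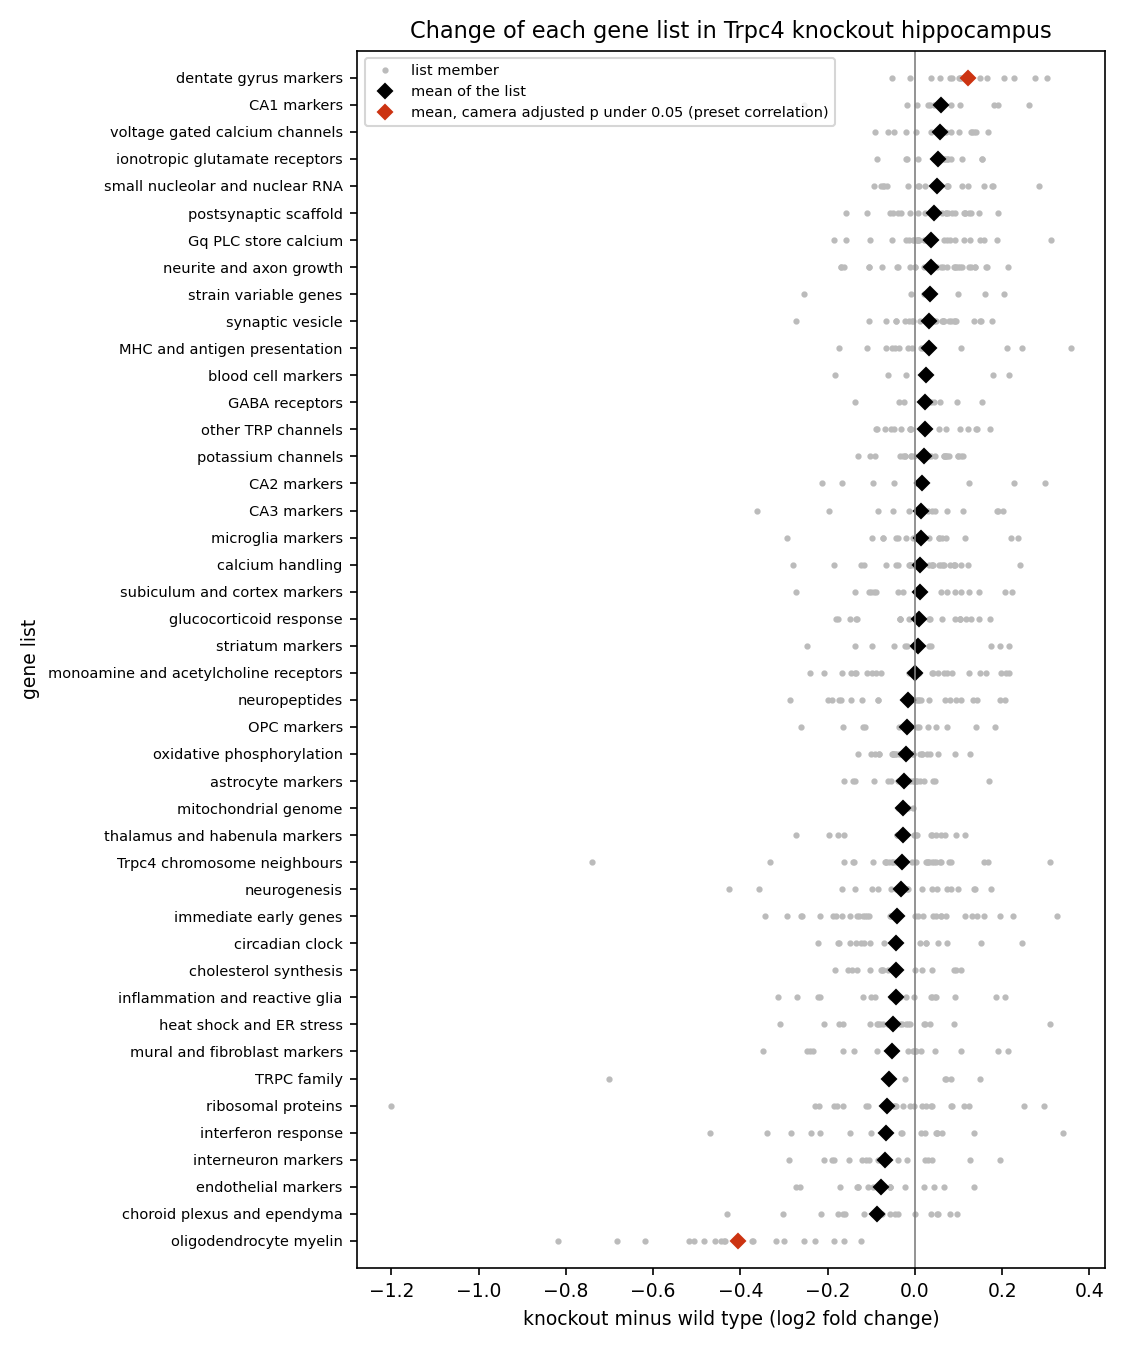
Log2 difference between knockout and wild type for the members of the 44 gene lists (grey points) with the mean of each list (diamonds), sorted by mean. The oligodendrocyte and myelin list lies lowest at -0.41 and the dentate gyrus list highest at 0.12, and these 2 are coloured as called by camera with the preset correlation.

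Genes beside Trpc4 on chromosome 3 were compared because DNA of the targeted strain can stay next to a knockout allele. Of 30 measured genes in the list of neighbours, 29 lie on chromosome 3 in the reference table. Of the 30, 15 were higher and 15 lower, with a median of -0.0014, and 0 passed over all genes or adjusted over the list alone. The meiosis gene Sohlh2 differed by 0.31 ± 0.12 and the cyclin gene Ccna1 by -0.33 ± 0.15, both with mean signals below the median of all probe sets. Stoml3 had the largest difference of the list, -0.74 ± 0.36, within a wide spread between samples, from -0.47 without wild-type replicate 2 to -1.12 without knockout replicate 3. Of 187 genes within 20 Mb of Trpc4, 0 passed over that set alone, where the lowest adjusted p was 0.155.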

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

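The fit with the myelin score as a covariate, and the estimated correlation within the other settings, were chosen only after the result was seen. The fall of Trpc4 kept its direction and an unadjusted p under 0.05 under every alternative run for it, between -0.77 and -0.65 when single samples were left out, and no neighbour of Trpc4 was called under any. The count of 0 genes at the adjusted threshold became 1 with trend and robust variance (Trpc4, adjusted p 0.0378), and it was 0 to 1 without single samples (Rps13, adjusted p 0.00897, without knockout replicate 1). Under each other alternative run the lowest adjusted p was 0.0779 or higher. The 44 genes past an unadjusted p and 1.5-fold became 16 with only probe sets above the median, 381 with all probe sets, 779 at 1.2-fold, 3 at 2-fold, 27 at an unadjusted p of 0.01, 272 with the myelin covariate, and 50 to 78 without single samples. The first 2 came with fewer or more tested features and the next 3 with other limits. With all probe sets the count rose more than in proportion to the features (22180 genes to 41345 probe sets). The cause of this and of the other changes was not tested. The myelin score itself differed between wild type and knockout (0.20 against -0.20), so the 272 cannot be read as genes uncovered by removing a myelin effect. The 2 lists called became 4 with trend and robust variance, 5 with probe sets above the median, 4 with list members above the median, 0 with an estimated correlation, alone or within each other setting tried with it, 0 with directional fry, and 1 (without knockout replicate 2) to 5 (without knockout replicate 3) when samples were left out. Mixed fry called 3 lists (TRPC, CA3 and ribosomal protein genes), each with 1 gene past the threshold adjusted over the list alone (Trpc4, Iyd and Rps15). Of 1098 alternative values of 93 named genes, 1092 kept their direction and their side of the adjusted threshold, and 5 turned direction. Since 0 genes passed that threshold in the main comparison, keeping the side was nearly fixed in advance. Genes named for groups that do not overlap also cannot turn when a sample is left out. The count is therefore no measure of how firm these values are. Without single samples Trpc7 ranged from -0.0485 to 0.17 (-0.02 without wild-type replicate 3) and Trpc2 from -0.12 to 0.0506 (0.02 and 0.04 without knockout replicates 1 and 3). With the replicate block, 0 genes passed, 1316 had an unadjusted p under 0.05, 42 also passed 1.5-fold, 3 lists were called (choroid plexus and ependyma in addition, adjusted p 0.0399) and Trpc4 stood at -0.70 (p 0.000158). The numbers were not taken as pairs, because the labels do not say that they mark litters or days. Deviations of same-numbered samples correlated at 0.067, 0.035 and -0.004 across genes, and those of differently numbered samples at -0.061 to 0.027. Not every sample correlated best with its own number, and these small values do not decide whether samples were paired.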

Other observations

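The 3 counts over other splits of the samples for genes and lists were planned, and the tests on the myelin list and on dim probe sets were chosen only after the result was seen. For dim probe sets, the use of an interval to read the share was also added after the share was seen.

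Camera called none of the inflammatory and immune lists in knockout hippocampus. Interferon response genes were lower for 9 of 17 (camera adjusted p 0.343), with Ifit2 at -0.34 ± 0.11, Oasl2 at -0.47 ± 0.18 and Usp18 at 0.34 ± 0.12 (log2 difference ± standard error). In antigen presentation (adjusted p 0.926) the immunoproteasome gene Psmb9 differed by 0.36 ± 0.10, and among inflammation and reactive glia genes (adjusted p 0.381) the chemokine gene Ccl3 differed by -0.31 ± 0.10. Neurogenesis genes were lower for 10 of 19 (adjusted p 0.590), with the cell cycle kinase gene Cdk1 at -0.43 ± 0.11 and Eomes, of intermediate progenitors, at -0.36 ± 0.20. Heat shock and endoplasmic reticulum stress genes were lower for 17 of 22 (adjusted p 0.0927, and 0.0302 with trend and robust variance or 0.0190 with only probe sets above the median, where the estimated correlation gave 0.620 and 0.717), among them the chaperone genes Calr at -0.21 ± 0.09 and Hspa1a at -0.31 ± 0.13. Single samples moved some of these values, Eomes to -0.17 without wild-type replicate 3 and -0.18 without knockout replicate 1, Oasl2 to -0.30 and Hspa1a to -0.21 without wild-type replicate 2, and Ifit2 to -0.22 without wild-type replicate 1. Of the genes named here, all but Calr and Hspa1a had mean signals below the median of all probe sets (4.72). In these 5 lists 0 genes passed adjusted over the list alone.

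Camera called no metabolic list. Oxidative phosphorylation genes were lower for 18 of 26 (adjusted p 0.325), with Sdhc at -0.13 ± 0.07. Cholesterol synthesis genes, which myelinating cells use strongly, were lower for 10 of 15 (adjusted p 0.261), and Sc5d differed by -0.18 ± 0.08. Genes known to vary between mouse strains were higher for 6 of 8 (adjusted p 0.778), with Glo1 at -0.25 ± 0.10. Camera also called none of the neuropeptide (adjusted p 0.590), thalamus and habenula (0.608), striatum (0.840) and blood cell (0.973) lists. The 7 measured mitochondrial genome genes of the list lay between -0.04 and -0.0033. Outside it, ND6, the mitochondrial gene on the other strand, differed by -0.69 ± 0.18 (adjusted p 0.849). The transcription factor gene Zic1 differed by -0.96 ± 0.29 (adjusted p 0.849).

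For the lower myelin signals, lists of equal signal level drawn at random reached at the lowest -0.0940, against -0.41 for the myelin list, which argues against a level-dependent bias of the normalization. White matter differing from sample to sample, whatever the genotype, stays open. The list mean ranged over 0.577 within knockout, more than the 0.406 between genotypes, but over only 0.0676 within wild type. A range within a genotype and a difference of means are unlike measures. Spread in the knockout alone cannot separate such sampling from an effect of genotype that varies between samples. Of the 10 splits of the 6 samples 1, the real one, gave a shift as large, with 0.352 the highest of the other splits, and 10 splits are too few for a share under 0.05. Camera with the preset correlation called the myelin list in 5 of the 10 splits and the dentate list in 3, the real one included. A loss of myelin or oligodendrocytes in the knockout stays open and was not tested.

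Of the 44 genes past an unadjusted p and 1.5-fold, 63.6% had a mean signal below the median of all probe sets, against 41.5% of all genes. In the other splits that share was higher, 65.4 to 92.9%. The exact binomial 95% interval of the real one, 47.8 to 77.6%, overlaps this range. That interval treats the 44 genes as independent, which genes measured on the same arrays are not, so it cannot decide the question. Above the median signal lay 16 of the 44 genes, against 2 to 11 in the other splits, and 3 of the 44 belong to the myelin list. Trpc4, the deleted gene, is among the 16 and so among the 44, and it adds to both counts of the real split. For the genes below it, noise of dim probe sets cannot be told apart from an effect of genotype. The number of splits with as many genes was 1 of 10 (44, highest other 42), at the adjusted threshold 10 of 10 (0, highest other 0), and for called lists 6 of 10 (2, highest other 7), all with too few splits for a share under 0.05.

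The ribosomal protein gene Rps15 had the lowest p of all genes, at -1.20 ± 0.15 (p 4.93e-05, adjusted p 0.738), from a dim 4.31 in wild type to 3.11 in knockout. The list of 24 ribosomal protein genes, Rps15 included, was not called by camera (adjusted p 0.259) and passed the mixed fry test (adjusted p 0.0146), with 1 gene, Rps15, past the threshold adjusted over the list alone.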
